A study of Saccharomyces cerevisiae with 37 samples.

How the data were processed

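The data were 37 libraries of 3'-end sequencing (Lexogen QuantSeq) from budding yeast, which the labels give as haploid and of the BY4741 background. Per the labels, a wild-type strain (WT) and a strain with a 25x array of GFA1 behind the CUP1 promoter (the array strain) were grown in rich medium, washed, and kept for about 2 h in copper-free minimal medium. A sample was taken at 0 min, copper sulfate was added, and further samples followed every 5 min up to 30 min, then at 45 and at 60 min. The treatment note gives 500 uM copper and the growth note gives the same figure in mM; the unit was not settled here. Replicate numbers were read as cultures sampled over time, from the growth note: WT cultures 1 and 2 and array cultures 1 and 2 had all 9 times, and WT culture 3 had 0 min alone. The sources used here do not say whether the array replicates were 2 isolates or 2 cultures of 1 isolate, or whether WT culture 3 was grown alongside the others. No culture without copper was sampled after 0 min, so copper and time in the medium were not separated.

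The deposited values were raw read counts per gene, whole numbers in 1 column per library. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.10a, SAMtools 1.10 and HTSeq 2.0.2 with genome build R64; the strand setting and annotation release were not given in the sources used here. No unique molecular identifiers are mentioned, so copies made by PCR could not be told from separate molecules, and the counting intervals and floors below cover counting error only. The table lists 6464 genes, of which 6461 matched the reference annotation by identifier. HTSeq's summary entries, such as reads aligned at several places, were kept out of library sizes. Such reads are absent from gene counts, so genes with near-identical copies lose counts.

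Gene counts per library ran from 305028 (WT 0 min replicate 1) to 887971 (WT 0 min replicate 3), and 5394 to 5641 genes had at least 1 count. After 0 min, WT libraries held 471950 to 630994 and array libraries 402378 to 641502; array 0 min libraries held 616894 and 662865. Reads in genes made up 36.6% to 54.6% of all listed reads. The floor of 3 counts corresponded to 3.17 to 7.98 CPM (counts scaled by library size) in single libraries.

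Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr at a minimum count of 10, TMM scaling, quasi-likelihood F tests) in 1 fit of 18 strain and time groups. It had 19 residual degrees of freedom, 4995 tested genes and a biological coefficient of variation of 19.6%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each comparison. DESeq2 1.42.0 and limma 3.58.1 (voom with culture as random effect) served as alternatives, along with DESeq2 size factors, other filters on low counts, culture as a block, GFA1 and CUP1 left out, only the libraries compared, and each culture left out in turn. Levels are means of CPM with SD and n libraries; adjusted p-values in the text are from edgeR unless another tool is named. Groups at 0 counts were given bounds from a floor of 3 counts over the group, and groups with 1 to 3 counts were given a ratio with a 95% counting interval.

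Gene lists were tested with camera from limma on log CPM with a preset correlation of 0.01 between genes. The adjustment ran over 253 tests, 23 lists in 11 comparisons. Each list was also tested with a correlation estimated from the data and with fry. Of 24 lists fixed beforehand, the alpha-cell list had only 1 tested member and was not tested as a list. The ribosomal protein rule also took in RPP1, a subunit of RNase P; PIR2 and FKS2 were matched as HSP150 and GSC2. Lists of haploid-specific genes and of small nuclear and nucleolar RNA genes, all 30 min comparisons, and genes that differed at all 9 times were added after results had been seen, and had their own adjustment.

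The genes named were fixed by rule. They were GFA1, CUP1, the measured members of the copper and marker lists, members of called lists, and the genes with the smallest p in the interaction at any time. Up to 10 (time) or 8 (strain) genes were also taken at each end of the log2 fold changes. These had to be called, have at least 10 CPM in 1 group, and have every library of 1 group on the same side of every library of the other. Counts of these genes that kept their call therefore come from genes chosen for agreement between libraries. Comparisons, lists, tests and alternatives were chosen before the data were examined, except those named here or with the alternatives as added.

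The 20 pairs of libraries within groups were compared for identity: chi-square per degree of freedom was 1.37 to 35.3, so none was counted as deposited more than once. Culture identity across times was checked through the difference between replicate 1 and replicate 2: its correlation between times, across genes, had a median of 0.095 in WT and 0.073 in the array strain over 36 pairs of times each, and -0.022 between strains at the same time. It was above 0.1 in 18 pairs in WT (highest 0.568) and in 14 in the array strain (highest 0.208). The lowest values were -0.394 in WT and -0.171 in the array strain. As both signs occurred, a lasting difference between cultures was not shown. The fit used throughout had no culture block, as planned, and culture as a replicate block was an alternative. Named genes and lists whose call ended with it are given beside their results or with the alternatives. The same replicate number in the other strain was treated as a number only.

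The analysis was tested on simulated data built from the fitted means and dispersions. At 20 min against 0 min in WT, edgeR recovered 45.5% of 110 genes changed 2-fold and 89.8% of 88 changed 4-fold, with 4 false calls among 133. Between strains at 20 min it recovered 36.1% of 108 and 83.3% of 90, with 10 false among 124. Simulated genes varied independently, so the preset correlation of the list tests was not tested. No comparison had 3 libraries on each side, so labels were not reshuffled.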

Results

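In WT, copper was followed within 20 min by higher general stress and cell wall transcripts and lower ribosome assembly transcripts, as lists tested by camera with a preset correlation. At 20 min the general stress list had adjusted p = 0.169 with an estimated correlation, and so had the cell wall list. The ribosome assembly list had adjusted p = 0.0325 with an estimated correlation. At 60 min in WT the general stress list was not called. The cell wall list was higher (adjusted p = 0.659 with an estimated correlation), but not called without WT 0 min replicate 1. The ribosome assembly list was then higher by camera (adjusted p = 0.576 with an estimated correlation). How many genes still differed was left open, as 31 were called at 60 min with all libraries and 571 without WT 0 min replicate 1. The array strain carried more GFA1 transcript than WT at all 9 times, and its GFA1 rose further after copper. It also carried more LEU2 and more a-cell and haploid-specific mating transcripts, at 0 min as well as after copper. In principal components of all libraries, the first 2 components held 31.1% and 20.1% of the variance, and WT 0 min replicate 1 stood alone at 79.1 on the first.

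GFA1 encodes glutamine:fructose-6-phosphate amidotransferase, which makes the first committed precursor of chitin (chromosome XI, 243220 to 245373). Its transcript was 11.9-fold higher in the array strain than in WT already at 0 min (log2 3.57, SE 0.45, adjusted p = 8.79e-06). Without WT 0 min replicate 1, which had the most GFA1 of the WT 0 min libraries, the difference was 25.7-fold (log2 4.68, adjusted p = 2.13e-11). The difference was 58.1-fold at 20 min (log2 5.86, adjusted p = 1.93e-07), 92.3-fold at 30 min (log2 6.53, adjusted p = 2.88e-08) and 45.9-fold at 60 min (log2 5.52, SE 0.57, adjusted p = 4.2e-07). At the times between, log2 differences were 4.14 (5 min), 5.30 (10 min), 5.90 (15 min), 6.44 (25 min) and 6.04 (45 min), each called. Within the array strain GFA1 went from 1889 ± 128 CPM at 0 min to 12030 ± 828 at 20 min, 20850 ± 766 at 30 min and 8111 ± 184 at 60 min (n = 2 libraries each). Against 0 min these were log2 fold changes of 2.67 (adjusted p = 0.028), 3.46 (adjusted p = 0.00147) and 2.10 (adjusted p = 0.114, not called). Those at 5 min (0.72), 10 min (1.75, adjusted p = 0.301) and 15 min (2.32, adjusted p = 0.185) were not called either, while those at 25 min (3.26) and 45 min (2.65) were. With culture as a replicate block the rises of GFA1 at 10 min (adjusted p = 0.0128) and 60 min (2.11, adjusted p = 0.000623) were called, as the one at 60 min was without WT 0 min replicate 1 (adjusted p = 1.21e-05) or WT 0 min replicate 3 (adjusted p = 0.000869).

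The call for GFA1 at 20 min in the array strain ended without any 1 of the 4 array libraries compared: adjusted p = 0.562 without array 0 min replicate 1, 0.31 without array 0 min replicate 2, 0.218 without array 20 min replicate 1 and 0.193 without array 20 min replicate 2. It ended with voom too (2.67, adjusted p = 0.147). At 30 min it ended without array 0 min replicate 1 (3.40, adjusted p = 0.0842). The log2 fold change of GFA1 itself stayed between 2.60 and 2.75 at 20 min in these 4 fits. Single array libraries held 1798 and 1979 CPM at 0 min and 11450 and 12620 CPM at 20 min. With all array libraries kept, the rise at 20 min stayed called without WT 0 min replicate 1 (adjusted p = 5.09e-07), replicate 2 (0.0264) or replicate 3 (4.26e-05). The culture block gave adjusted p = 4.6e-05. No WT library is in this comparison, but the fit shares the spread of a gene over all groups. At a log2 fold change of 2.67, the SE was 0.493 with all libraries and 0.486 without WT 0 min replicate 2. It was 0.266 without WT 0 min replicate 1 and 0.315 without WT 0 min replicate 3. Calls for the rise in the array strain thus rested in part on the spread of GFA1 among WT 0 min libraries. The call at 20 min ended without WT culture 2 (2.67). The higher level of GFA1 in the array strain than in WT was called at 0, 20 and 60 min in each fit that kept the gene, except at 0 min with only the libraries compared (adjusted p = 0.888).

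In WT, GFA1 was at 166 ± 160 CPM at 0 min (n = 3; 343, 121 and 32.8 in the single libraries), 207 ± 5.33 at 20 min and 177 ± 57.1 at 60 min (n = 2). The change at 20 min was not called (log2 0.38, adjusted p = 0.672). Without WT 0 min replicate 1, the library with the most GFA1, GFA1 rose 2.82-fold at 20 min, against 1.31-fold with it, and was called (adjusted p = 0.00269). At 30 min and 60 min the same held, with adjusted p = 0.0013 and 0.0104 without that library, against 0.599 and 0.96 with it. Without WT 0 min replicate 3, the library with the least GFA1, the log2 fold changes were -0.14, -0.02 and -0.37 at 20, 30 and 60 min, none called. With culture as a replicate block they were -0.11, 0.03 and -0.35. At 60 min the sign also turned without WT 0 min replicate 2 or WT 60 min replicate 1 (-0.21). The direction of GFA1 in WT therefore rested on the choice of libraries.

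Tested as an interaction, GFA1 was 2.29 log2 units higher in the response of the array strain than in that of WT at 20 min (adjusted p = 0.831), 2.96 at 30 min (adjusted p = 0.0768) and 1.95 at 60 min (adjusted p = 1), so a different response was not called. With culture as a replicate block, WT 0 min replicate 3 had its own term and did not enter the WT 0 min level. That setting and the fit without this library are therefore not separate support. A different response was called with culture as a replicate block (adjusted p = 0.00725, 0.000265 and 0.0435) and without WT 0 min replicate 3 (adjusted p = 0.00576, 0.000177 and 0.0409). At 30 min it was also called without WT 0 min replicate 1 (1.85, adjusted p = 0.0456) or replicate 2 (3.12, adjusted p = 0.00851), and by DESeq2 with all libraries (2.99, adjusted p = 0.00754). At that time leaving out any 1 WT 0 min library gave a call. At 20 and 60 min GFA1 was not called without replicate 1 (1.18, adjusted p = 0.571, and 0.84, adjusted p = 0.519) or replicate 2 (adjusted p = 0.11 and 0.512).

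**Figure D1:**
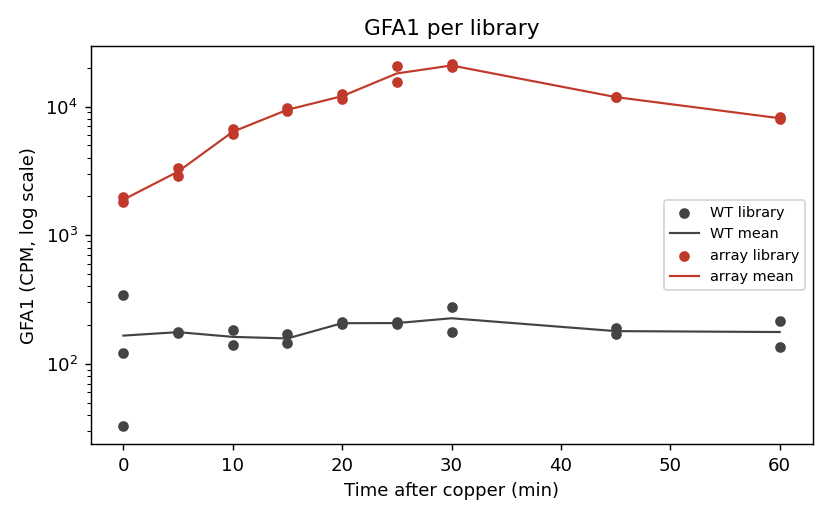
GFA1 in CPM on a log axis against time after copper, points for libraries and lines for means. The array strain lies above WT at each of the 9 times.

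CUP1-1 and CUP1-2, identical metallothionein genes whose promoter drives the array (chromosome VIII, 212535 to 212720 and 214533 to 214718), were listed at 0 counts in all 37 libraries, so they have no value here. CRS5, the other copper metallothionein gene, annotated here as a pseudogene (chromosome XV, 389213 to 389422), rose at 20 min in WT from 36.7 ± 30.9 (n = 3) to 95.6 ± 3.63 CPM (n = 2, log2 1.19, SE 0.34, adjusted p = 0.036). The call for CRS5 ended without WT 0 min replicate 2 (log2 0.98, adjusted p = 0.0654), WT 20 min replicate 1 (1.12) or WT 20 min replicate 2 (1.23). The rise itself remained in each of these fits. In the array strain its log2 fold change was 1.33 at 20 min (adjusted p = 0.547), and its difference between strains at 60 min was -0.14. SOD1, copper/zinc superoxide dismutase, was not called at 20 min in WT (0.19, adjusted p = 0.619) or the array strain (0.02), nor between strains at 60 min (-0.02). The copper detoxification list was not called at 20 min in WT (adjusted p = 0.157).

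Genes for copper uptake under Mac1 were not called. The copper transporter CTR3 had log2 fold changes of 1.22 in WT (adjusted p = 0.379) and 0.32 in the array strain at 20 min, and 0.68 between strains at 60 min. The reductase FRE1 had -0.98 (adjusted p = 0.213), -0.59 and 1.25 (adjusted p = 0.215), and REE1 had -0.14, -0.01 and 0.30 in the same comparisons. CTR1, FRE7 and IRC7 were too low to test, with 50, 17 and 62 counts over all WT libraries and 48, 23 and 44 over all array libraries. The copper uptake list was not called at 20 min in WT (adjusted p = 0.96) or in any other comparison.

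Over the time course in WT, 437 genes were called by edgeR, or 912 without WT 0 min replicate 1 and 659 without WT 0 min replicate 2. At 5 min no gene was called by edgeR or voom, 4 were called by DESeq2, and 553 had an unadjusted p under 0.05. Leaving out WT 0 min replicate 2 gave 256 at 5 min. As lists, general stress genes were higher (camera, adjusted p = 0.00146, adjusted p = 0.659 with an estimated correlation) and Hsf1 chaperone genes lower (adjusted p = 0.000435, adjusted p = 0.249 with an estimated correlation). Among the chaperones no gene was called over all genes, and 4 fell adjusted over the list alone. Proteasome genes were lower (adjusted p = 0.0242, adjusted p = 0.659 with an estimated correlation). The calls for chaperones (adjusted p = 0.114) and the proteasome (adjusted p = 0.871) ended with culture as a replicate block.

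Further lists at 5 min in WT were called only with WT 0 min replicate 1 included. Ribosome assembly genes were lower (adjusted p = 0.000677, 0.0733 without it, adjusted p = 0.659 with an estimated correlation). Cell wall genes were higher (adjusted p = 0.00295, 0.0912 without it, adjusted p = 0.63 with an estimated correlation), with 1 gene adjusted over the list alone. Glycolysis genes were higher (adjusted p = 6.75e-06, 0.0956 without it, adjusted p = 0.659 with an estimated correlation). Zap1 zinc genes were higher (adjusted p = 0.0229, 0.68 without it, adjusted p = 0.659 with an estimated correlation), and so were Gcn4 amino acid genes (adjusted p = 0.0481, 0.573 without it, adjusted p = 0.666 with an estimated correlation). Ribosomal protein genes were higher (adjusted p = 8.05e-11, adjusted p = 0.678 with an estimated correlation), and turned lower without that library (adjusted p = 0.416).

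Among genes that met the naming rule at 20 min in WT, those with the largest rises included TSL1, SED1 and SPS100. Those with the largest decreases included LTV1 and ENP2. TSL1, a subunit of trehalose synthase, rose from 40.2 ± 20.5 (n = 3) to 214 ± 27.5 CPM (n = 2, log2 2.41, SE 0.52, adjusted p = 0.007), and the glycogen debranching gene GDB1 rose by 2.08 (adjusted p = 0.0459). The cell wall glycoprotein gene SED1 rose from 66.6 ± 50.2 to 296 ± 50.3 CPM (adjusted p = 0.0125), and the spore wall gene SPS100 rose by 3.06 (SE 0.64, adjusted p = 0.00608). PHM7 rose by 2.35 (adjusted p = 0.0106), TOH1 by 2.31 (adjusted p = 0.00911), YPR145C-A by 2.41 (adjusted p = 0.000684) and QCR2, a subunit of respiratory complex III, by 2.06 (adjusted p = 0.0065). The hexose transporter gene HXT5 had 19 counts against 3, a ratio of 10.6 (3.13 to 56.1, adjusted p = 0.0157), and SPG4 had 16 against 3, a ratio of 8.96 (2.56 to 48.0, adjusted p = 0.042).

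LTV1, a factor for ribosomal small subunit export (chromosome XI, 176781 to 178172), went at 20 min in WT from 238 ± 59.0 (n = 3) to 81.9 ± 1.55 CPM (n = 2, log2 -1.52, SE 0.22, adjusted p = 0.000323). The helicase gene DBP8 fell by 1.59 (adjusted p = 0.00909), the nucleolar ENP2 by 1.30 (adjusted p = 0.000669), and the GTPase gene BMS1 by 1.29 (adjusted p = 0.0247). RSA3, another assembly gene, fell to 67.9 ± 14.1 from 204 ± 160 CPM (adjusted p = 0.0207). UTP23 fell to 58.6 ± 0.927 CPM from 142 ± 37.0 (adjusted p = 0.00793), and SYO1, an importer of ribosomal proteins, had 11.2 ± 3.95 against 29.0 ± 9.43 (adjusted p = 0.0459). YBL028C fell by 1.44 (adjusted p = 0.000395), YBR242W by 1.42 (adjusted p = 0.0157), and the siderophore transporter gene SIT1 by 1.32 (adjusted p = 0.00308).

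In all, 277 genes were called at 20 min in WT, 106 higher and 171 lower, with 139 at an absolute log2 fold change of at least 1. With only the libraries compared, no gene was called. With culture as a replicate block the count was 464, and 227 of the 277 were among them. HXT5 (adjusted p = 0.0607), SPG4 (adjusted p = 0.0832) and GDB1 (adjusted p = 0.0528) lost their call with it. The count was 419 without WT 0 min replicate 1 (227 of them among the 277), 690 without WT 0 min replicate 2, 55 without WT 20 min replicate 1 and 15 without WT 20 min replicate 2. Of the 20 genes named above, 18 kept their call without WT 0 min replicate 1 (RSA3 and BMS1 lost it), 19 without WT 0 min replicate 2 (SYO1 lost it), 14 without WT 0 min replicate 3 (HXT5, SPG4, PHM7, SED1, GDB1 and DBP8 lost it), 8 without WT 20 min replicate 1 and 4 (YPR145C-A, LTV1, YBL028C and ENP2) without WT 20 min replicate 2.

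As lists at 20 min in WT, 21 of 39 ribosome assembly genes fell, 31 adjusted over the list alone (camera, adjusted p = 6.71e-19, adjusted p = 0.0325 with an estimated correlation). Among them were MAK16 (-1.19), NOC2 (-1.17), RLP7 (-1.17) and RPF1 (-1.10). Of 22 general stress genes 8 rose, 14 adjusted over the list alone (adjusted p = 8.99e-10, adjusted p = 0.169 with an estimated correlation). These included TSL1, the catalase gene CTT1 (1.93), the aldehyde dehydrogenase gene ALD3 (1.77) and YGP1 (1.73). Of 11 cell wall integrity genes 5 rose, 9 adjusted over the list alone (adjusted p = 3.19e-07, adjusted p = 0.169 with an estimated correlation): SED1, HSP150 (2.06), NCW2 (1.76), GSC2 and the kinase gene SLT2 (0.87). Respiration genes were higher, with QCR2 and CIT1 (0.92) called of 27 (adjusted p = 0.00146, adjusted p = 0.659 with an estimated correlation). Glycolysis genes were higher too, with 0 of 16 called by edgeR (adjusted p = 1.2e-05, adjusted p = 0.659 with an estimated correlation). Ribosomal protein genes were higher with 0 of 138 called (adjusted p = 6.48e-06, adjusted p = 0.83 with an estimated correlation) and lower without WT 0 min replicate 1 (adjusted p = 0.143).

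Other lists at 20 min in WT were not called, although single members were. The chitin synthase gene CHS1 rose (adjusted p = 0.000395; hexosamine and chitin list, adjusted p = 0.193), as did the peroxiredoxin gene PRX1 (adjusted p = 0.0157; oxidative stress list, adjusted p = 0.0957) and HIS4 (0.88), while CPA1 fell (-1.13, amino acid list, adjusted p = 0.232). Adjusted p was 0.487 for iron uptake, 0.237 for zinc, 0.246 for chaperones, 0.246 for sulfur assimilation, 0.508 for the proteasome, 0.96 for the unfolded protein response, 0.809 for mRNP assembly and export, and 0.96 for phosphate. It was 0.0774 for a-cell genes, 0.96 for meiosis, 0.694 for marker genes, 0.459 for mitochondrial genes, 0.281 for haploid-specific genes and 0.849 for small nuclear and nucleolar RNA genes. The mRNP, hexosamine, copper uptake and meiosis lists were not called by camera in any comparison.

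At 60 min in WT, genes above their 0 min level included GSC2 and ALD3, and genes below it included HSC82, AHA1, CPR6 and SGT2. GSC2, a glucan synthase subunit (chromosome VII, 548264 to 553951), rose from 102 ± 18.5 (n = 3) to 380 ± 21.8 CPM (n = 2, log2 1.91, SE 0.19, adjusted p = 8.64e-07). SPS100 rose by 3.12 (adjusted p = 0.0156), YPR145C-A by 2.42 (adjusted p = 0.00455), SPS18 by 1.91 (adjusted p = 0.0466) and YMR075C-A by 1.42 (adjusted p = 0.0062). The small heat shock gene HSP26 rose to 25.5 ± 10.7 CPM from 4.95 ± 2.37 (adjusted p = 0.0324), the Hsp70 gene SSA4 to 646 ± 96.8 from 182 ± 155 (adjusted p = 0.0062). ALD3 rose to 153 ± 44.9 from 33.5 ± 33.0 (adjusted p = 0.00911). OYE3, an NADPH oxidoreductase gene, rose by 2.05 (adjusted p = 0.0392), and the cell wall mannoprotein gene FIT2, which helps hold siderophores, by 1.58 (adjusted p = 0.0269).

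HSC82, the constitutive Hsp90 gene (chromosome XIII, 632355 to 634472), fell at 60 min in WT from 4430 ± 94.9 (n = 3) to 2467 ± 50.7 CPM (n = 2, adjusted p = 0.00774). The Hsp90 co-chaperone genes AHA1 (-0.80, adjusted p = 0.0392) and CPR6 (-0.78, adjusted p = 0.0454) also fell, as did the co-chaperone gene SGT2 (-1.04, adjusted p = 0.0154). The transcription factor gene CIN5 fell by 1.88 (adjusted p = 0.0154), the heme synthesis gene HEM13 by 1.53 (adjusted p = 0.0481), SIT1 by 1.48 (adjusted p = 0.0062), the deacetylase gene HST3 by 1.42 (adjusted p = 0.0102) and the cytochrome oxidase assembly gene COA4 by 1.21 (adjusted p = 0.0062).

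The count at 60 min in WT was 31, 22 higher and 9 lower, with 23 at an absolute log2 fold change of at least 1. It depended on single libraries: 571 without WT 0 min replicate 1 (31 of them shared), 61 without WT 0 min replicate 2, 6 without WT 60 min replicate 1 and 2 without WT 60 min replicate 2. It was 32 with culture as a replicate block, but only 20 of the 31 were among them. SPS100 (adjusted p = 0.11), OYE3 (adjusted p = 0.108), SPS18 (adjusted p = 0.194), CIN5 (adjusted p = 0.0777), HEM13 (adjusted p = 0.0523), HST3 (adjusted p = 0.0716), SGT2 (adjusted p = 0.0839), AHA1 (adjusted p = 0.154) and CPR6 (adjusted p = 0.154) lost their call with the block. The same 9 genes lost it without WT 0 min replicate 3, which the block takes out of the WT 0 min level. These fits are therefore not separate support. Of 19 named genes, 15 kept their call without WT 0 min replicate 2, 10 without WT 0 min replicate 3, 4 without WT 60 min replicate 1 and 2 (GSC2 and YMR075C-A) without WT 60 min replicate 2. Between 20 and 60 min in WT, 322 genes were called, 221 higher and 101 lower at 60 min. That count was 737 without WT 0 min replicate 1, 122 and 107 without WT 20 min replicates 1 and 2, and 86 and 175 without WT 60 min replicates 1 and 2.

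Sulfur assimilation was the list called at 60 min in WT with the lowest p under an estimated correlation: 2 of 17 genes rose, MET1 (1.16) and MET10 (1.02), 5 adjusted over the list alone (adjusted p = 3.16e-08, adjusted p = 0.00823 with an estimated correlation). Chaperone genes were lower (adjusted p = 1.21e-08, adjusted p = 0.0325 with an estimated correlation), with 1 rise and 3 falls of 24, and 2 rises and 9 falls adjusted over the list alone. Ribosome assembly genes were higher, with NOG2 called (1.15, adjusted p = 3.79e-05, adjusted p = 0.576 with an estimated correlation). Proteasome genes were lower (adjusted p = 0.0192, adjusted p = 0.659 with an estimated correlation) and mitochondrial genes higher (adjusted p = 0.00974, adjusted p = 0.716 with an estimated correlation). Small nuclear and nucleolar RNA genes were higher (adjusted p = 0.0198, adjusted p = 0.646 with an estimated correlation), but not with culture as a replicate block (adjusted p = 0.511). With that block the calls for proteasome (adjusted p = 0.969) and mitochondrial genes (adjusted p = 0.935) ended too.

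Some lists at 60 min in WT rested on WT 0 min replicate 1. Cell wall genes were higher, with GSC2 called and 2 rises and 1 fall adjusted over the list alone (adjusted p = 0.0146, 0.429 without it, adjusted p = 0.659 with an estimated correlation). Amino acid genes were higher (adjusted p = 0.0306, 0.772 without it, adjusted p = 0.659 with an estimated correlation). Ribosomal protein genes were higher (adjusted p = 0.00101, adjusted p = 0.891 with an estimated correlation) and turned lower without it (adjusted p = 1.6e-06), with 25 lower and 2 higher genes called. Not called were general stress, with HSP26 and ALD3 up (adjusted p = 0.694), zinc, with the transporter gene ZRT2 up (1.14, adjusted p = 0.0721), oxidative stress (adjusted p = 0.0913) and iron uptake (adjusted p = 0.703).

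**Figure D2:**
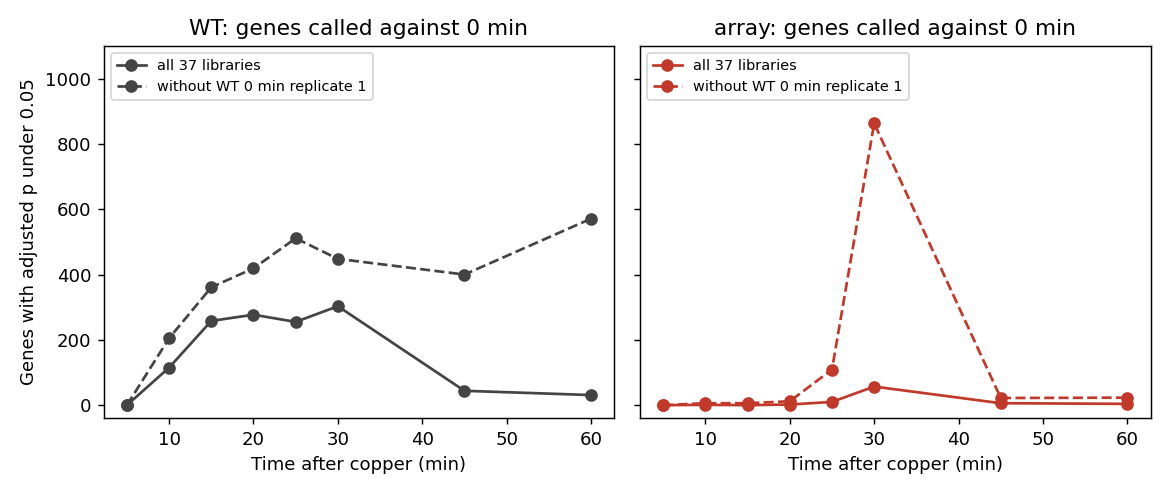
Genes with an adjusted p under 0.05 at each time against 0 min, in WT and in the array strain. Solid lines use all 37 libraries and dashed lines leave out WT 0 min replicate 1.

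In the array strain few genes were called, and those at 60 min included a cell wall gene shared with WT. GSC2 rose from 75.3 ± 8.45 to 278 ± 14.9 CPM (n = 2, log2 1.88, SE 0.22, adjusted p = 2.67e-05). HO, the mating-type endonuclease gene, rose from 340 ± 11.2 to 931 ± 99.7 CPM (adjusted p = 0.00232), the zinc transporter gene ZRT2 rose by 1.34 (SE 0.22, adjusted p = 0.0029), and CPR6 fell by 1.00 (adjusted p = 0.0275). These 4 were all that was called at 60 min, with 228 at an unadjusted p under 0.05, and 14 with culture as a replicate block. GSC2 kept its call without each single array library at 0 or 60 min. The count was 1 without array 0 min replicate 1, 2 without array 60 min replicate 1, 1 without array 0 min replicate 2, and 23 without WT 0 min replicate 1. Of the other 3 genes, HO lost its call without either array 0 min library, ZRT2 without those or array 60 min replicate 1, and CPR6 without any of the 4.

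Over the time course the array strain had 31 called genes, 474 without WT 0 min replicate 1 and 125 with culture as a replicate block. The count was 12 without array 0 min replicate 2, 19, 17 and 18 without replicate 1 at 5, 10 and 30 min, and 17 and 14 without replicate 2 at 30 and 45 min. At 20 min 2 genes were called, GFA1 among them, with 301 at an unadjusted p under 0.05. This was 12 without WT 0 min replicate 1, 4 with the replicate block, and 0 by edgeR without any 1 of array 0 min replicates 1 and 2 or array 20 min replicates 1 and 2. At 5 min no gene was called by edgeR, DESeq2 or voom (98 at an unadjusted p under 0.05). Between 20 and 60 min none was called by edgeR, with 330 at an unadjusted p under 0.05, 8 by DESeq2 and 4 by voom. That became 19 without WT 0 min replicate 1 and 11 with the replicate block.

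As lists, general stress genes of the array strain were higher at 5 min (adjusted p = 1.79e-06, adjusted p = 0.35 with an estimated correlation) and at 20 min (adjusted p = 1.67e-14, adjusted p = 0.0601 with an estimated correlation), where 0 of 22 were called by edgeR and 5 rose adjusted over the list alone. Ribosome assembly genes were lower at 5 min (adjusted p = 0.00098, adjusted p = 0.659 with an estimated correlation) and at 20 min (adjusted p = 2e-19, adjusted p = 0.0325 with an estimated correlation), where 0 of 39 were called and 3 fell adjusted over the list alone. Cell wall genes were higher at 5 min (adjusted p = 0.0102, adjusted p = 0.659 with an estimated correlation), 20 min (adjusted p = 4.13e-05, adjusted p = 0.314 with an estimated correlation) and 60 min (adjusted p = 0.0229, adjusted p = 0.659 with an estimated correlation). Chaperone genes were lower at 5 min (adjusted p = 0.0229, adjusted p = 0.635 with an estimated correlation) and at 60 min (adjusted p = 9.76e-07, adjusted p = 0.0753 with an estimated correlation). Iron uptake genes were lower at 20 min (adjusted p = 0.00425, adjusted p = 0.495 with an estimated correlation). At 60 min small nuclear and nucleolar RNA genes were higher (adjusted p = 0.0483, adjusted p = 0.663 with an estimated correlation). Sulfur genes were higher as well (adjusted p = 0.0481; 0.0571 without WT 0 min replicate 1, adjusted p = 0.508 with an estimated correlation).

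**Figure D3:**
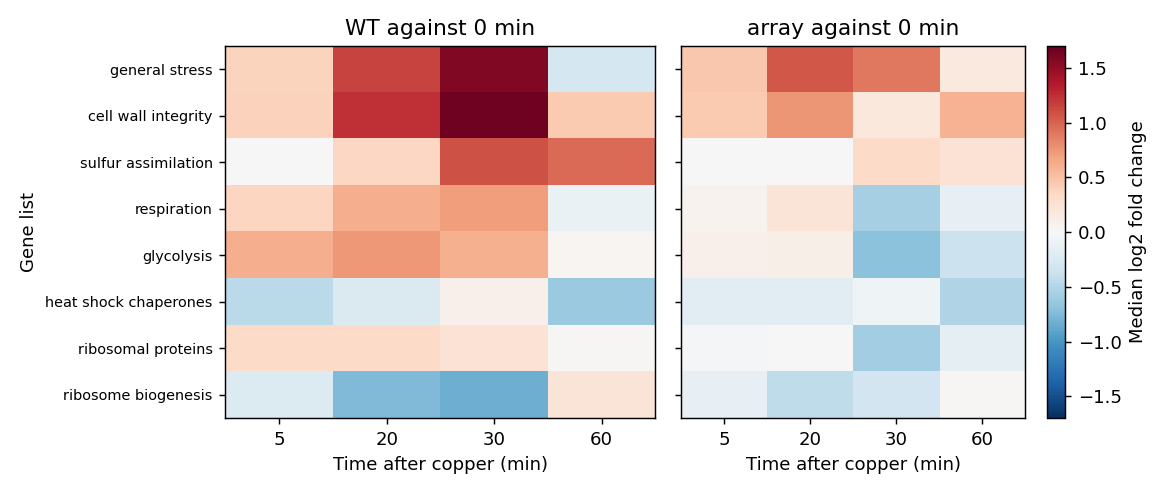
Median log2 fold change against 0 min of 8 gene lists at 5, 20, 30 and 60 min in WT and in the array strain. The direction of the ribosomal protein list in WT at each of these times turns when WT 0 min replicate 1 is left out.

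Between strains at 0 min, before copper, the array strain had more transcript of GFA1, LEU2 and a-cell genes such as STE2, and less of LEU1, HSP42 and GSY2. LEU2, a leucine synthesis gene absent from the BY4741 background (chromosome III, 91324 to 92418), had 642 counts in the array strain (542 ± 20.3 CPM, n = 2) and 0 in WT (n = 3), at least 352-fold higher (adjusted p = 3.1e-10). LEU1, which acts in the same pathway, was lower at 74.0 ± 16.7 against 362 ± 61.0 CPM (log2 -2.29, SE 0.22, adjusted p = 4.67e-08). The pheromone receptor gene STE2 (chromosome VI, 82580 to 83875) stood at 319 ± 3.37 against 30.3 ± 7.35 CPM (adjusted p = 7.5e-10). The a-factor genes MFA1 (907 ± 70.4 against 75.1 ± 66.4 CPM, adjusted p = 0.000129) and MFA2 (3.47, adjusted p = 3.46e-07) and the cell fusion gene FUS1 (94.4 ± 6.44 against 9.38 ± 1.31 CPM, adjusted p = 1.34e-08) were higher too. YCL021W-A was higher by 3.49 (adjusted p = 6.16e-05), and RDT1 had 14 counts against 2, a ratio of 11.5 (2.65 to 104, adjusted p = 0.0476).

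IME4, a methyltransferase gene of meiosis (chromosome VII, 142246 to 144048), had 62 counts in WT at 0 min and 0 in the array strain, at least 12.6-fold lower (adjusted p = 0.000275). The polyamine transporter gene TPO2 (-2.42, adjusted p = 0.00714), the chaperone gene HSP42 (-2.31, adjusted p = 0.000271), CIN5 (-2.20, adjusted p = 0.00109), BDH2 (-2.12, adjusted p = 0.00669), the glycogen synthase gene GSY2 (-2.06, adjusted p = 0.0028) and UIP4 (-2.38, adjusted p = 0.037) were lower as well. In all, 172 genes were called, 79 higher and 93 lower, with 125 at an absolute log2 difference of at least 1, and 432 with culture as a replicate block, with 143 of the 172 among them. The count was 882 without WT 0 min replicate 2, 273 without WT 0 min replicate 3, and 40 and 78 without array 0 min replicates 1 and 2. Of 16 named genes, 14 kept their call without WT 0 min replicate 1 or without array 0 min replicate 2 (RDT1 and UIP4 lost it), and 11 without array 0 min replicate 1 (RDT1, TPO2, UIP4, BDH2 and GSY2 lost it).

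At 20 min the array strain had more transcript of HO, GPA1 and FAR1, and less of the stress genes HSP12 and CTT1. HO (chromosome IV, 46271 to 48031) stood at 423 ± 52.7 CPM in the array strain and 25.1 ± 4.30 in WT (n = 2, log2 4.07, SE 0.29, adjusted p = 7.38e-10). LEU2 had 686 counts against 4 (log2 7.44, adjusted p = 9.45e-09). The pheromone pathway genes GPA1 (3.38, adjusted p = 3.93e-06) and FAR1 (2.88, adjusted p = 0.000976) were higher. NDJ1, AFB1 and NFG1 had ratios of 16.2 (2.49 to 682, adjusted p = 0.0347), 11.4 (2.77 to 99.8, adjusted p = 0.0361) and 9.18 (2.18 to 82.0, adjusted p = 0.014) over 1 to 3 WT counts. HSP12, a membrane stress protein gene, was at 42.8 ± 30.3 against 469 ± 9.65 CPM (adjusted p = 0.035), and CTT1 was lower by 2.73 log2 units (adjusted p = 4.31e-06). FMP16 (-2.96, adjusted p = 0.0395), EGO4 (-2.83, adjusted p = 0.035), BDH2 (-2.77, adjusted p = 0.000774) and MSC1 (-2.21, adjusted p = 0.00634) were lower. SPS100 had 1 count against 22, a ratio of 0.0491 (0.00119 to 0.304, adjusted p = 0.0126). IME4 had 1 against 20, a ratio of 0.054 (0.0013 to 0.338, adjusted p = 0.036).

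The count between strains at 20 min was 83, 42 higher and 41 lower, with 71 at an absolute log2 difference of at least 1. It was 177 without WT 0 min replicate 1, 33 and 34 without WT 20 min replicates 1 and 2, and 26 and 39 without array 20 min replicates 1 and 2. Of 16 named genes, 9, 8, 6 and 10 kept their call without these 4 libraries in turn; LEU2, GFA1, HO, GPA1, FAR1 and CTT1 kept it in each. NDJ1, AFB1, HSP12, FMP16 and EGO4 lost it in each. NFG1 lost it without either WT 20 min library or array 20 min replicate 1, SPS100 without WT 20 min replicate 2 or array 20 min replicate 1, and IME4 without these or array 20 min replicate 2. BDH2 lost it without array 20 min replicate 1, and MSC1 without replicate 1 of either strain.

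At 60 min the array strain had more transcript of HO, GPA1, STE2 and AGA2, and less of CTT1 and ALD3, than WT. LEU2 had 740 counts against 2, a ratio of 350 (96.5 to 2894, adjusted p = 7.23e-09), while HIS3, another marker gene, had a log2 difference of -0.14. HO stood at 931 ± 99.7 against 64.1 ± 19.1 CPM (n = 2, adjusted p = 2.96e-10). GPA1 stood at 62.3 ± 6.08 against 4.96 ± 4.25 (adjusted p = 1.18e-05) and STE2 at 183 ± 15.6 against 27.6 ± 0.442 (adjusted p = 4.5e-06). The agglutinin gene AGA2 (3.40, adjusted p = 0.00151), MFA1 (3.35, adjusted p = 0.00694) and MFA2 (3.04, adjusted p = 5.49e-05) were higher. IME4 had 0 counts against 32, at least 11.3-fold lower (adjusted p = 0.00151), and SPS100 had 1 against 20, a ratio of 0.0473 (0.00114 to 0.296, adjusted p = 0.0175). CTT1 (-2.69, adjusted p = 0.000175), RTC2 (-2.44, adjusted p = 0.0295), ALD3 (-2.19, adjusted p = 0.0117), YMR085W (-2.06, adjusted p = 0.0293), LEU1 (-1.99, adjusted p = 5.06e-06) and PHM8 (-1.81, adjusted p = 0.0293) were lower.

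There were 43 called genes between strains at 60 min, 26 higher and 17 lower, 66 with culture as a replicate block and 153 without WT 0 min replicate 1. The count was 25 and 18 without WT 60 min replicates 1 and 2, and 23 and 22 without array 60 min replicates 1 and 2. Of 16 named genes, 12, 9, 9 and 11 kept their call without these 4 libraries in turn. SPS100, RTC2 and PHM8 lost it in each, ALD3 and YMR085W without WT 60 min replicate 2 or either array library, MFA1 without WT 60 min replicate 1, replicate 2 or array 60 min replicate 1, and AGA2 without the last 2 of these.

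The a-cell list was higher in the array strain at 0 min (6 of 6 genes, adjusted p = 2.92e-12, adjusted p = 0.000175 with an estimated correlation), at 20 min (6 of 6, adjusted p = 1.4e-15) and at 60 min (5 of 6, adjusted p = 1.4e-14). Its protease gene BAR1 differed by 3.16, 2.48 and 2.51, the a-factor exporter gene STE6 by 2.44, 2.63 and 1.84, and ASG7 by 2.34, 2.30 and, not called, 0.96. Of 10 haploid-specific genes, 8 were higher at 0 min, 9 adjusted over the list alone (adjusted p = 3.3e-13), 7 at 20 min (adjusted p = 2.09e-23) and 7 at 60 min (adjusted p = 5.03e-26). At 0 min these were HO (3.17), the meiosis repressor gene RME1 (2.74), GPA1 (2.54), AXL1 (2.39), FAR1 (2.22), STE4 (2.10), STE18 (2.04) and STE5 (1.97).

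**Figure D4:**
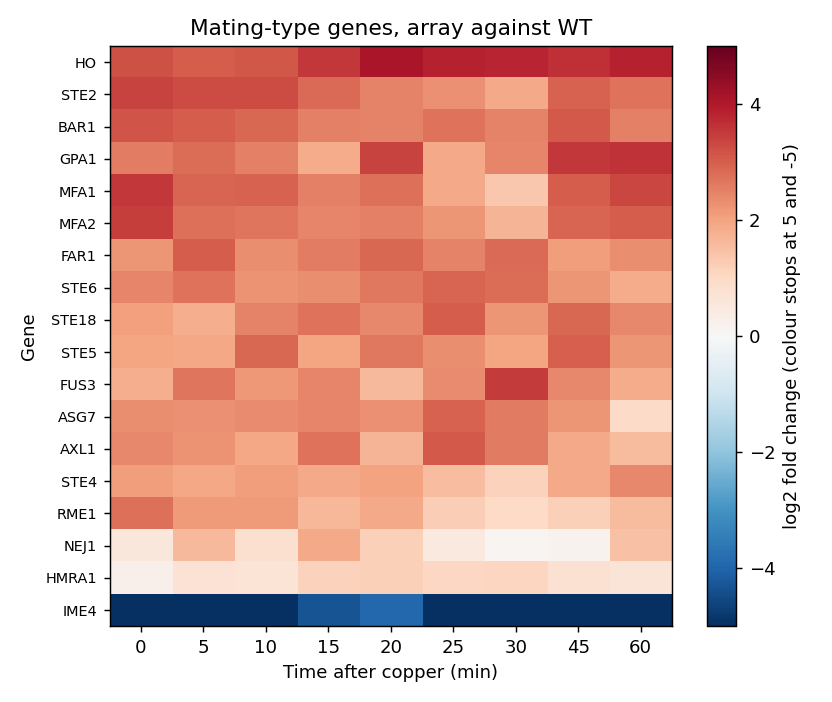
Log2 difference between the array strain and WT of 18 mating and cell type genes at the 9 times. Colours stop at 5 and -5.

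General stress genes were lower in the array strain at 0 min (7 of 22, 12 adjusted over the list alone, adjusted p = 2.65e-07, adjusted p = 0.282 with an estimated correlation), 20 min (6 of 22, 15 adjusted over the list alone, adjusted p = 1.19e-15, adjusted p = 0.0456 with an estimated correlation) and 60 min (2 of 22, 6 adjusted over the list alone, adjusted p = 9.76e-07, adjusted p = 0.325 with an estimated correlation). Ribosome assembly genes were higher at 20 min, with 0 called by edgeR and 8 adjusted over the list alone (adjusted p = 5.35e-11, adjusted p = 0.166 with an estimated correlation). Respiration genes were lower then (adjusted p = 0.0192, adjusted p = 0.678 with an estimated correlation). Iron uptake genes were higher at 60 min, with SIT1 called (1.21) and 3 adjusted over the list alone (adjusted p = 2.54e-05, adjusted p = 0.169 with an estimated correlation). Mitochondrial genes were lower at 60 min (adjusted p = 0.0229, adjusted p = 0.786 with an estimated correlation).

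Ribosomal protein genes were higher in the array strain at 0 min (adjusted p = 7.6e-20, adjusted p = 0.63 with an estimated correlation), 20 min (adjusted p = 8.27e-08, adjusted p = 0.764 with an estimated correlation) and 60 min (adjusted p = 6.15e-12, adjusted p = 0.666 with an estimated correlation). The marker list was higher through LEU2 at 0 min (adjusted p = 0.00457, adjusted p = 0.101 with an estimated correlation), 20 min (adjusted p = 0.000289, adjusted p = 0.0325 with an estimated correlation) and 60 min (adjusted p = 0.00031). Without WT 0 min replicate 1 the calls ended for amino acid genes at 0 min (adjusted p = 0.0306, 0.275 without it, adjusted p = 0.659 with an estimated correlation) and glycolysis genes at 0 min (adjusted p = 0.00101, 0.234 without it, adjusted p = 0.678 with an estimated correlation). The same held for genes of the unfolded protein response at 20 min (adjusted p = 0.0394, 0.0956 without it, adjusted p = 0.177 with an estimated correlation) and 60 min (adjusted p = 0.0429, 0.0998 without it, adjusted p = 0.177 with an estimated correlation).

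Whether the strains differed in their response to copper was tested as an interaction. At any time no gene was called by edgeR or voom, with 202 at an unadjusted p under 0.05 and 3 by DESeq2; 1 was called with culture as a replicate block, and 1 without WT 0 min replicate 2 or WT 0 min replicate 3. At 20 min edgeR, DESeq2 and voom called none (282 at an unadjusted p under 0.05), and at 60 min none (128 at an unadjusted p under 0.05); at each of these times GFA1 alone was called with the replicate block, and GFA1 alone without WT 0 min replicate 3. Genes such as CTT1 were therefore not shown to respond differently in the 2 strains.

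As lists in the interaction at 20 min, ribosomal protein genes were lower in the array strain (adjusted p = 1.79e-06, adjusted p = 0.828 with an estimated correlation) and turned higher without WT 0 min replicate 1 (adjusted p = 0.285). Calls that ended without that library were ribosome assembly, higher (adjusted p = 0.00172, 0.0571 without it, adjusted p = 0.659 with an estimated correlation), and cell wall, lower (adjusted p = 0.0102, 0.105 without it, adjusted p = 0.659 with an estimated correlation). The same held for glycolysis, lower (adjusted p = 0.000106, 0.0687 without it, adjusted p = 0.659 with an estimated correlation), and respiration, lower (adjusted p = 0.0428, 0.069 without it, adjusted p = 0.716 with an estimated correlation). The call for respiration ended with culture as a replicate block as well (adjusted p = 0.136).

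As lists at 60 min, the interaction was lower for sulfur genes (adjusted p = 0.00307, adjusted p = 0.177 with an estimated correlation) and ribosome assembly genes (adjusted p = 0.000208, adjusted p = 0.635 with an estimated correlation). Calls for amino acid genes (adjusted p = 0.000404, adjusted p = 0.424 with an estimated correlation), oxidative stress genes (adjusted p = 0.0394, adjusted p = 0.651 with an estimated correlation) and a-cell genes (adjusted p = 0.0137, adjusted p = 0.177 with an estimated correlation) ended without WT 0 min replicate 1 (0.13, 0.416 and 0.0952). Those for ribosomal protein genes (adjusted p = 7.2e-06, adjusted p = 0.83 with an estimated correlation) and glycolysis genes (adjusted p = 0.0168, adjusted p = 0.828 with an estimated correlation) turned higher without it (0.00392 and 0.565). The calls for oxidative stress (adjusted p = 0.0537), ribosome assembly (adjusted p = 0.0621) and a-cell genes (adjusted p = 0.0537) ended with culture as a replicate block.

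Log2 fold changes of the 2 strains, each against its own 0 min, had Pearson correlations across 4995 genes of 0.181 at 5 min, 0.357 at 20 min and 0.314 at 60 min. Over the 443 genes called over time in either strain, these were 0.463, 0.74 and 0.504. Over all genes, the correlation at 5 min was 0.115, 0.087 and 0.077 without WT culture 2, WT culture 3 and array culture 2. At 20 min it was 0.223 without array culture 1, and at 60 min 0.135 and 0.182 without WT culture 2 and array culture 2. Genes are not independent replicates, so no p is given.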

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

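The tests that weigh explanations and the 30 min comparisons were chosen only after the results were seen. So were the genes at all 9 times and the fits without single libraries. Other items added then are named with the methods and with the alternatives. SNZ1, a vitamin B6 synthesis gene (chromosome XIII, 458408 to 459301), was singled out by a difference between the strains in their response to copper. At 30 min, a time added after the data were seen, the responses differed by -2.14 log2 units, lower in the array strain (SE 0.38, adjusted p = 0.0307, edgeR), with 56.7 ± 9.08 CPM against 110 ± 15.4 in WT (n = 2). These CPM are levels at 30 min, whereas the difference of responses also takes in the 0 min levels, WT 0 min replicate 1 among them. SNZ1 was the only gene called in that test, with 1181 at an unadjusted p under 0.05, 56 by DESeq2 and 11 by voom. The call for SNZ1 ended with the share of reads in genes as a covariate (log2 -1.765, adjusted p = 0.291). It also ended with WT 0 min replicates 1 and 3 left out (-1.877), and with culture as a replicate block without WT 0 min replicate 1 (-1.973, adjusted p = 0.0905). The difference itself stayed negative in each of these fits. Culture as a replicate block takes WT 0 min replicate 3 out of the WT 0 min level. Replicate 1 then weighs more in that level, as it does without replicate 2 or 3. Counts from such fits cannot be read as responses particular to a strain, since replicate 1 stood apart from the others. The count was 692 with that block, and 11, 711 and 310 without WT 0 min replicates 1, 2 and 3. It was 0 without WT 30 min replicate 1, WT 30 min replicate 2, array 0 min replicate 1, array 30 min replicate 1 or array 30 min replicate 2. At 20 min SNZ1 had -1.45 (adjusted p = 0.831).

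Reads that aligned at several places, which the gene counts leave out, were singled out as a signal in data outside the comparisons. In the array strain their mean share of listed reads was 11.68% at 15 min, 13.00% at 25 min, 13.17% at 30 min, 12.35% at 45 min and 12.03% at 60 min, each with both libraries above the 0 min libraries of that strain (10.04% and 11.4%). In WT no time had both libraries above all 0 min libraries, but this rests on WT 0 min replicate 1 alone (12.77%). Against the other WT 0 min libraries (10.16% and 6.17%), both WT libraries were higher at each time from 10 to 60 min (lowest 10.48%), so a difference between strains is not shown. CUP1-1 and CUP1-2, which are identical, lie among the genes whose reads would fall here. Which genes these reads came from was not tested.

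The lower a-cell and haploid-specific transcripts of WT, against labels that give haploid MATa for both strains, were the first pattern weighed. Scaling between libraries is argued against, since it moves all genes alike, and the median difference of the 16 genes stood at least 2.31 above that of all tested genes at each of the 9 times. Alpha cells among WT are argued against too: their pheromone gene MF(ALPHA)1 had 1 count in 19 WT libraries, 0.0127% of the MFA1 level of the array strain. A candidate explanation is a/alpha cells in the WT cultures, since HMRA1, whose sequence is shared with the MATa locus, was higher in the array strain at 9 of 9 times, by a mean of 0.836 (0.673 to 1.02 between single cultures, n = 2 per strain, and called at 4 of the 9 times), and IME4, repressed in haploid cells, had 262 counts in WT and 2 in the array strain. A change of the mating pathway through the strain construction was not tested and stays open.

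The second pattern was WT 0 min replicate 1, which correlated at 0.717 and 0.698 with the other WT 0 min libraries, against 0.937 between those. Its lower depth is argued against, since replicate 2 thinned to 305028 counts kept a correlation of 0.908 with replicate 3. Whether it was a library of another group under this label was not settled. Its highest correlation with any library was 0.823 (WT 60 min replicate 1), below the lowest of 0.902 between replicates of other groups. A library that differs in quality could fall below that value in any group. A trend with transcript length is argued against as the whole cause, since removing it moved the correlation with replicate 2 from 0.716 to 0.73. Its share of reads in genes (36.6%) was the lowest and its share outside annotated genes (50.6%) the highest of the 37 libraries, and 51 small nuclear and nucleolar RNA genes deviated by a median of 1.18, so its RNA or library may play a part, as may its culture, and no test here separates these.

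The third pattern was the number of called genes in the array strain at 30 min, 57 against 0 to 10 at the other times. With the share of reads in genes as a covariate the count was 24, against 22 at 20 min, so this share and time cannot be told apart, since the share moves with time in that strain. The axis on which WT 0 min replicate 1 stood apart is a candidate cause, since array log2 fold changes at 30 min correlated with that deviation at 0.604 across genes, against 0.043 at 20 min. The correlation was 0.454 at 25 min, 0.285 at 45 min and 0.284 at 60 min. A response of the cells to high GFA1, which peaked at 30 min, stays open and was not tested.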

How the results depend on the processing

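Chosen only after the data were seen were the fits without single libraries, without WT 0 min replicates 1 and 3, with the share of reads in genes as a covariate, and with culture as a replicate block without WT 0 min replicate 1. The 30 min results, the genes at all 9 times and the list tests without WT 0 min replicate 1 were added then too. Where a count changed, the cause was not tested, except as follows. Fits with fewer libraries or genes hold less data by construction. Leaving out WT 0 min replicate 1 lowered the biological coefficient of variation of the shared fit from 19.61% to 13.88%. That value is shared by comparisons that do not use this library, such as array 30 min against 0 min (57 genes called with it, 863 without it). Where a group was left with 1 library, it was assumed to vary like the others. CUP1 has no value under any setting, and GFA1 has none where it was left out. For the interaction at any time, a fit to only the libraries compared equals the fit to all libraries. The higher GFA1 of the array strain at 60 min kept its direction and call throughout, at 5.22 to 5.92 without single cultures or libraries and 5.54 with culture as a replicate block. A filter of 10 CPM in 2 libraries moved no count by more than 1.5 times.

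With DESeq2 size factors, array 60 min against 20 min called 1 gene. With DESeq2 tests, WT 5 min called 4, the array time course 113, array 20 min 5, array 30 min 120, array 60 min 13, array 60 min against 20 min 8, and the interaction 3 at any time and 56 at 30 min. With no filter, the interaction at 30 min called 5. With voom, WT 60 min called 49, the array time course 51, array 20 min 1, array 60 min 8, array 60 min against 20 min 4, and the interaction at 30 min 11. With GFA1 and CUP1 left out, array 20 min called 1.

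Similar counts hid changes in single named genes. With DESeq2 tests, 243 of the 277 genes of WT 20 min were called, 29 of the 31 of WT 60 min, and 150 of 172, 65 of 83 and 39 of 43 between strains at 0, 20 and 60 min. HXT5, SPS100, SPG4 and PHM7 at WT 20 min were given no adjusted p by DESeq2, and SYO1 was not called. Calls also ended for HSP26 and SPS18 at WT 60 min, RDT1 and UIP4 between strains at 0 min, and SPS100 and PHM8 at 60 min. Between strains at 20 min they ended for NDJ1, AFB1, NFG1, SPS100, IME4 and HSP12 (adjusted p = 0.0555). With voom, 75 of 83 and 33 of 43 were called between strains at 20 and 60 min. Calls ended for GFA1 at array 20 min (adjusted p = 0.147), SYO1 at WT 20 min, HEM13 at WT 60 min and UIP4 between strains at 0 min. They also ended for HSP12, FMP16 and EGO4 at 20 min, and RTC2, YMR085W and PHM8 at 60 min. With no filter they ended for SPG4 and SYO1 at WT 20 min, SPS18, AHA1 and CPR6 at WT 60 min, CPR6 at array 60 min and RDT1 between strains at 0 min. SPS18 at WT 60 min lost its call with a filter of 10 CPM in 2 libraries (adjusted p = 0.0519). With the share of reads in genes as a covariate, RDT1 and UIP4 between strains at 0 min and SNZ1 in the interaction at 30 min lost theirs, and GFA1 at WT 20 min gained a call (adjusted p = 0.0215).

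With culture as a replicate block, WT 20 min called 464 genes, WT 30 min 513, the array time course 125, array 20 min 4, array 30 min 249, array 60 min 14 and array 60 min against 20 min 11. The strains differed in 432 genes at 0 min, 369 at 30 min and 66 at 60 min, and the interaction called 1 at any time, 1 at 20 min, 692 at 30 min and 1 at 60 min. The block leaves differences between cultures of the same strain out of the spread, so its counts between strains can be too high. It also takes WT 0 min replicate 3 out of the WT 0 min level. No other count moved by more than 1.5 times with it (WT time course 599, WT 60 min 32, strains at 20 min 119), although only 20 of the 31 genes of WT 60 min were among the 32. With the replicate number as a replicate block across strains, which only the numbers link, the strains differed in 295 genes at 0 min and 337 at 30 min.

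With only the libraries compared, the WT time course called 119, WT 20 min 0, WT 30 min 0, WT 60 min 0 and WT 60 min against 20 min 1192. The array time course called 1150, array 5 min 1, array 20 min 56, array 30 min 1379, array 60 min 207 and array 60 min against 20 min 99. The strains differed in 3 genes at 0 min, 364 at 20 min, 862 at 30 min and 631 at 60 min, and in 3 at all 9 times, and the interaction at 30 min called 0.

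Without WT 0 min replicates 1 and 3, the WT time course called 777, WT 20 min 101, WT 30 min 149, WT 60 min 96 and WT 60 min against 20 min 835. The array time course called 663, array 20 min 26, array 30 min 977, array 60 min 32 and array 60 min against 20 min 42. The strains differed in 67 genes at 0 min, 239 at 20 min, 741 at 30 min and 212 at 60 min, and the interaction called 1 at any time, 1 at 20 min and 1 at 60 min.

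With culture as a replicate block and WT 0 min replicate 1 left out, the WT time course called 911, WT 20 min 166, WT 60 min 78 and WT 60 min against 20 min 966. The array time course called 930, array 20 min 40, array 30 min 1109, array 60 min 46 and array 60 min against 20 min 47. The strains differed in 77 genes at 0 min, 319 at 20 min, 853 at 30 min, 294 at 60 min and 43 at all 9 times, and the interaction called 1 at any time, 1 at 20 min and 1 at 60 min.

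With the share of reads in genes as a covariate, WT 5 min called 2, WT 20 min 427, WT 30 min 595, WT 60 min 255, the array time course 64, array 20 min 22, array 30 min 24, array 60 min 20 and array 60 min against 20 min 15. The strains differed in 181 genes at 20 min, and the interaction called 0 at 30 min and 1 at 60 min. Among only the genes called over time, the correlation of responses was 0.74 at 20 min and 0.463 at 5 min. Of 66 called list tests, 10 were called with an estimated correlation, 20 by directional fry and 19 by mixed fry. Among all 253 list tests, directional fry called 24 and mixed fry 26.

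Without single cultures, or single libraries of the groups compared, counts ranged from 61 to 912 for the WT time course, 0 to 256 for WT 5 min, 15 to 690 for WT 20 min, 53 to 562 for WT 30 min, 1 to 571 for WT 60 min and 32 to 403 for WT 60 min against 20 min. They ranged from 0 to 747 for the array time course, 0 to 20 for array 20 min, 0 to 965 for array 30 min, 0 to 24 for array 60 min and 0 to 31 for array 60 min against 20 min. Between strains they ranged from 25 to 882 at 0 min, 14 to 98 at 20 min, 12 to 298 at 30 min, 12 to 69 at 60 min and 7 to 26 at all 9 times. Leaving out WT 0 min replicate 1, which is in none of these groups, gave 737 for WT 60 min against 20 min, and 177, 651 and 153 between strains at 20, 30 and 60 min. For the interaction they ranged from 0 to 44 at any time, 0 to 1 at 20 min, 0 to 711 at 30 min and 0 to 1 at 60 min. The correlation of responses was 0.077 to 0.214 at 5 min, 0.223 to 0.341 at 20 min and 0.135 to 0.311 at 60 min.

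Some values changed sign. REE1 in array 20 min became 0.001 with DESeq2 size factors or tests, 0.006 with GFA1 and CUP1 left out and 0.19 with the share covariate. SOD1 between strains at 60 min became 0.012 with no filter, 0.008 with only the libraries compared and 0.013 without WT 0 min replicates 1 and 3. TRM12 in the interaction at 30 min became -0.021 with the replicate block, -0.049 without WT 0 min replicates 1 and 3, -0.076 with the block and WT 0 min replicate 1 left out, and -0.08 with the share. With the block, WT 20 min values became -0.107 for GFA1, 0.284 for REE1 and 0.131 for HIS3. SUN4 in the interaction at 20 min became 0.529 without WT 0 min replicates 1 and 3 and 0.41 with the block and WT 0 min replicate 1 left out. With the share, CTR3 (-0.051, from 0.68) and REE1 (-0.052) between strains at 60 min changed sign. Small nuclear and nucleolar RNA genes at WT 60 min changed direction with the block (adjusted p = 0.51079). Without WT 0 min replicate 1 the ribosomal protein list was called in the other direction at WT 30 min (adjusted p = 0.00878) and WT 60 min (adjusted p = 1.6e-06). The same held in the interaction at 60 min (adjusted p = 0.00392).

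Without single cultures or libraries, sign changes gave ranges of -0.405 to 0.244 for CRS5, -0.56 to 0.212 for HIS3, -0.383 to 0.896 for REE1 and -0.091 to 0.1 for SOD1 between strains at 60 min. In array 20 min they were -1.141 to 1.657 for CTR3 and -0.057 to 0.051 for REE1, and in WT 20 min -0.142 to 1.496 for GFA1, -0.271 to 0.135 for HIS3 and -0.496 to 0.266 for REE1. For TRM12 in the interaction at 30 min it was -0.11 to 0.227. For lists, adjusted p ranged from 7.11e-05 to 0.88838 for glycolysis in the interaction at 60 min, and 2.94e-08 to 0.51194 for small nuclear and nucleolar RNA genes at WT 60 min. For ribosomal proteins it was 3.02e-12 to 0.41594 at WT 5 min, 4.7e-09 to 0.99006 at WT 20 min, 1.07e-10 to 0.008782 at WT 30 min, 6.75e-09 to 0.009978 at WT 60 min, 2.86e-09 to 0.75403 in the interaction at 20 min and 1.06e-10 to 0.012411 at 60 min.

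Depth limits what low genes can show, as the floor of 3 counts is 3.17 to 7.98 CPM in single libraries.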

Other observations

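At 30 min, a time added after the data were seen, WT had more called genes than at any other time with all libraries, though not without WT 0 min replicate 1 (448 at 30 min, 571 at 60 min). Of 22 general stress genes 13 rose, 16 adjusted over the list alone (camera, adjusted p = 8.1e-14, adjusted p = 0.0448 with an estimated correlation), and 25 of 39 ribosome assembly genes fell, 28 adjusted over the list alone (adjusted p = 3.72e-23, adjusted p = 0.00753 with an estimated correlation). Of 17 sulfur assimilation genes 5 rose, 8 adjusted over the list alone (adjusted p = 2.35e-07, adjusted p = 0.00577 with an estimated correlation): MET2 (1.81), MET14 (2.15), MET10 (0.77), SUL2 (1.31) and MUP1 (1.08). Cell wall genes rose, 7 of 11 and 8 adjusted over the list alone (adjusted p = 3.02e-07, adjusted p = 0.113 with an estimated correlation). Yap1 oxidative stress genes were higher (adjusted p = 0.00126, adjusted p = 0.248 with an estimated correlation), with GSH1, OYE3, PRX1 and HBN1 called. Iron uptake genes were higher (adjusted p = 0.000431, adjusted p = 0.253 with an estimated correlation), with the copper transporter gene CCC2 (1.42) and FIT3 called. Copper detoxification genes were higher through CRS5 (112.9 CPM, adjusted p = 0.0198, adjusted p = 0.349 with an estimated correlation).

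The count at 30 min in WT was 303, 135 higher and 168 lower, and 513 with culture as a replicate block. It was 448 without WT 0 min replicate 1 (247 of them shared), 562 without WT 0 min replicate 2, and 102 and 76 without WT 30 min replicates 1 and 2. In the array strain it was 57, 31 higher and 26 lower, 249 with the replicate block and 863 without WT 0 min replicate 1. Without array 0 min replicates 1 and 2 it was 1 and 16, and without array 30 min replicates 1 and 2 it was 10 and 2. Between strains 186 genes were called, 95 higher and 91 lower, 369 with the replicate block and 651 without WT 0 min replicate 1. Without WT 30 min replicates 1 and 2 it was 49 and 79, and without array 30 min replicates 1 and 2 it was 36 and 84.

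The array libraries at 30 min had the lowest shares of reads in genes of that strain (40.8% and 42.7%, against 52.4% and 52.3% at 0 min). Their log2 fold changes correlated at 0.604 with the deviation of WT 0 min replicate 1. In the array strain at 30 min, general stress genes were higher, with the glycogen synthase gene GSY2 called (1.99, adjusted p = 3.07e-05, adjusted p = 0.375 with an estimated correlation) and 7 adjusted over the list alone. Ribosome assembly genes were lower, with the nucleolin gene NSR1 called (-1.69, adjusted p = 5.24e-06, adjusted p = 0.349 with an estimated correlation) and 6 adjusted over the list alone. Ribosomal protein genes were lower, with 0 called by edgeR and 75 without WT 0 min replicate 1 (adjusted p = 3.02e-08, adjusted p = 0.628 with an estimated correlation). Small nuclear and nucleolar RNA genes were higher (adjusted p = 0.00131, adjusted p = 0.52 with an estimated correlation). Phosphate genes (adjusted p = 0.00854, adjusted p = 0.394 with an estimated correlation) and glycolysis genes (adjusted p = 0.00205, adjusted p = 0.582 with an estimated correlation) were lower.

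Against WT at 30 min, the array strain had lower general stress genes, 13 of 22 and 19 adjusted over the list alone (adjusted p = 1.84e-16, adjusted p = 0.0242 with an estimated correlation). Ribosome assembly genes were higher, 7 of 39 and 25 adjusted over the list alone (adjusted p = 1.91e-12, adjusted p = 0.0717 with an estimated correlation). Small nuclear and nucleolar RNA genes were higher (adjusted p = 0.00313, adjusted p = 0.551 with an estimated correlation). The a-cell genes (5 of 6, adjusted p = 9.11e-09) and haploid-specific genes (7 of 10, adjusted p = 2.5e-13) were higher.

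Genes close to the threshold in the interaction at 30 min were the cell wall gene SUN4 (-3.26, adjusted p = 0.0704), the isocitrate dehydrogenase gene IDH1 (-1.63, adjusted p = 0.0704) and LSO2 (1.52, adjusted p = 0.0704), none of them called. SUN4 and IDH1 were called without WT 0 min replicate 1, by DESeq2 (adjusted p = 0.00885), by voom (adjusted p = 0.0427) and with no filter (adjusted p = 0.0498). With culture as a replicate block SUN4, IDH1, LSO2, CBF5, RPF1 (adjusted p = 0.0272), CHM7 (adjusted p = 0.0289) and SDH8 (adjusted p = 0.038) were called. LSO2 and CBF5 were called by DESeq2 and voom, and RPF1 by DESeq2. CHM7, CBF5 and RPF1 had adjusted p = 0.0925, and SDH8 (adjusted p = 0.109), MTR4 (0.62, adjusted p = 0.123), YDR210C-D (adjusted p = 0.164) and TRM12 (0.04, adjusted p = 0.972) were further from it. The correlation of the strains' log2 fold changes across 4995 genes at 30 min was -0.099, and over the 443 genes called over time in either strain it was 0.418. WT 0 min replicate 1 is part of the WT 0 min level, and array log2 fold changes at 30 min correlated with its deviation at 0.604. The negative value therefore does not show opposite responses of the strains.

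Genes higher in the array strain at all 9 times, a count made after the data were seen, were RDH54, LEU2, FUS1, HO, STE5, STE2, AGA2, GPA1, BAR1, FAR1, STE18, GFA1, STE6, YLR227W-B, SST2, MFA2, STE4 and AXL1, 18 in all, and 5 genes were lower at all 9. At 5 or more times, 37 genes were higher and 27 lower. LEU2 had 13 counts over the libraries of WT culture 2, and 0 over those of WT cultures 1 and 3. The marker gene URA3 had 0 counts in all libraries.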
